A study of Homo sapiens with 4 samples.

How the data were processed

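Total RNA of MOLM-13 cells was extracted with a column kit and made into libraries by a commercial provider, per the labels' protocols, which do not say whether polyadenylated RNA was selected or ribosomal RNA removed. Cells were transduced with lentivirus carrying CRISPR-Cas9 with a vector labelled EV or with sgKAT6A, per the labels. What EV contains, the guide sequence, the number of guides and the time of harvest are not given in the sources used here. Each of the 4 samples was assigned to its group and replicate number by its title, giving 2 EV and 2 sgKAT6A libraries.

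The authors deposited 1 table of TPM values per gene symbol, made with Salmon on hg38 per the submitters' processing notes. The Salmon version, the transcript annotation, the step from transcripts to genes and any filter are not given in the sources used here. Each library's TPM sums to 1000000 over 27800 symbols, of which 6449 are 0 in every library. TPM retains no read depth, so the precision of low values could not be computed, and no count model was used. TPM is a share of a whole, so an abundant RNA that differs between libraries moves the values of all other genes. The symbols MIR6723 and MIR4461 took between them 8.96% to 14.1% of each library. MIR6723 (chromosome 1, 632325 to 632413) lies in the pseudogene MTCO1P12 and MIR4461 (chromosome 5, 134928039 to 134928112) in the pseudogene MTND4LP30, both nuclear copies of mitochondrial genes in GENCODE 29 on GRCh38. Coordinates are from that annotation and not from the table, which has none.

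Values were used as deposited, without further scaling, as log2(TPM + 1). Genes with a mean of at least 1 TPM over all libraries were tested, 12603 in all. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. sgKAT6A and EV were compared with limma 3.58.1 in R 4.3.3, using a linear model and empirical Bayes moderated variances with a mean-variance trend (2 residual and 1.98 prior degrees of freedom). Tests were two-sided, adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Across libraries, the median log2 value of the tested genes spanned 0.13.

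The design, the alternatives, 33 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered the MOZ complex, other acetyltransferases, KMT2A fusion targets and cofactors, MYC targets, myeloid and stem cell programs, antigen presentation, interferon, NF-kB, p53, cell cycle, apoptosis, ribosomes, mitochondria, metabolism, stress responses and markers of other cell types. Lists with at least 5 genes tested, 31 of them, were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and the self-contained test fry were run beside it. The preset test treats genes as nearly independent, so its p-values can be far smaller than a test across 2 libraries per group allows. The always-named genes were KAT6A, KAT6B, MYC, MYB, HOXA9, HOXA10, MEIS1, FLT3, ITGAM, CD14, LYZ and MKI67. To these were added the 10 genes with the largest change in each direction among those past the threshold with no overlap of the groups. Where fewer passed, places went to the smallest unadjusted p. Up to 4 members with the smallest p were taken from each list described. Because this rule took only small RNA genes, the same rule was also applied to protein-coding genes, and this was decided after seeing the data. Gene classes came from NCBI RefSeq gene records by symbol or unambiguous synonym, which matched 12384 of the 12603 genes tested.

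The gene test and the list test were checked on simulated data with the means and spread of the real libraries, 12603 genes and 200 changed genes, in 10 runs. At the observed spread, 33.7% of 4-fold and 0.6% of 2-fold changes were recovered with 1.8 false calls per run, and the fitted differences had a slope of 1.00 on the true ones. A list shifted by -0.5 with independent genes was called in 100% of runs, with 0.1 other lists called per run. The simulated noise was independent between genes and libraries, whereas the estimated correlation within the MYC target list was 0.84 in the real data. These list rates therefore do not carry over to the real libraries. With 0.1 times the spread, 96.3% of 2-fold and 98.7% of 4-fold changes were recovered with 11.5 false calls per run.

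Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, removal of ribosomal protein genes, the variance model, each library left out, and the replicate number as a block. Mitochondrially encoded genes, which were to be removed with the ribosomal protein genes, are not present under their symbols in the table used. Alternatives with protein-coding genes only and without ribosomal RNA symbols were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.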

Results

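RNA was sequenced from MOLM-13, a human acute myeloid leukaemia cell line that carries a KMT2A-MLLT3 (MLL-AF9) fusion, after lentiviral delivery of CRISPR-Cas9. The 4 libraries fell into 2 groups of 2, one given a vector with a guide against KAT6A (sgKAT6A) and one given the vector labelled EV. KAT6A, also called MOZ, is a histone lysine acetyltransferase. The groups were compared here for the leukaemic expression program and for differentiation genes after KAT6A targeting. Expression was available in TPM, the share of a library's transcripts with a total of 1000000, for 27800 gene symbols, of which 12603 had a mean of at least 1 TPM and were tested. Read depth was unknown because TPM keeps no depth, so no counting interval or detection limit was computed. Between 12082 and 12630 genes reached 1 TPM in a library. The labels do not say whether replicates came from separate cultures or transductions, so p-values measure only the spread between these libraries.

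The libraries of a group lay far apart. The first principal component held 61.0% of the variance and placed EV replicate 1 at -39.6, sgKAT6A replicate 1 at -20.2, EV replicate 2 at 5.25 and sgKAT6A replicate 2 at 54.6. Among protein-coding genes, 444 differed more than 2-fold on the log2(TPM + 1) scale between the EV libraries and 541 between the sgKAT6A libraries. By comparison, 113 differed that much between sgKAT6A replicate 1 and EV replicate 1, and 207 between sgKAT6A replicate 2 and EV replicate 2. Of the pairs that share neither group nor number, sgKAT6A replicate 1 and EV replicate 2 differed in 223 genes (r = 0.982 across protein-coding genes, against 0.977 for the number 2 libraries) and sgKAT6A replicate 2 and EV replicate 1 in 1111 (r = 0.933). Library composition also differed. The 18S ribosomal RNA symbol RNA18SN5 was at 340 TPM in sgKAT6A replicate 2 against 10401 to 13751 TPM in the other libraries. Protein-coding genes took 77.9% and 78.2% of the TPM in the sgKAT6A libraries and 81.2% and 81.7% in the EV libraries. Small nuclear RNA genes took 0.103% and 0.325% of the TPM in EV and sgKAT6A replicate 1, and 0.402% and 2.31% in EV and sgKAT6A replicate 2. Differences within each replicate number are therefore given for KAT6A, MYC and the lists called, although each rests on a single library per group.

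**Figure D1:**
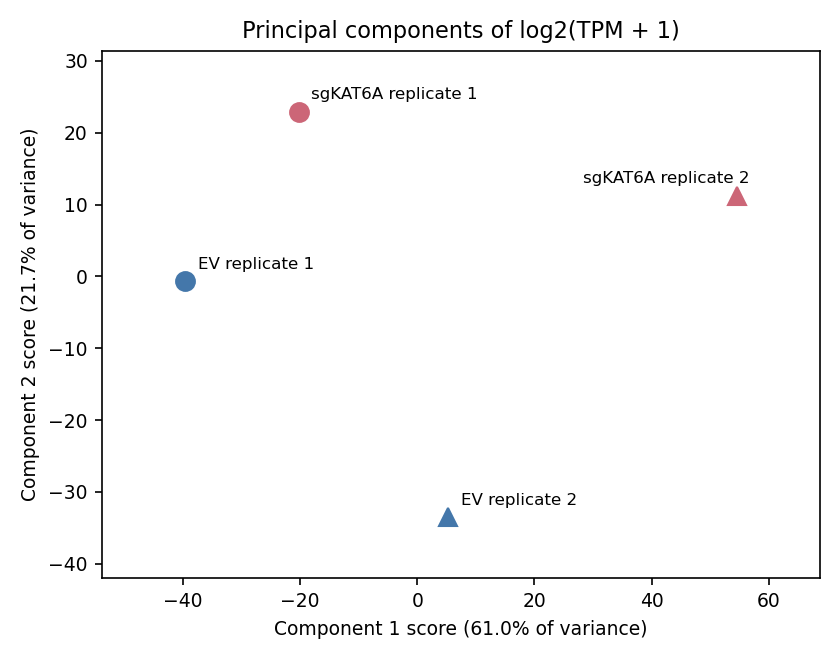
Principal components of log2(TPM + 1) over the 12603 genes tested, 1 point per library, with component scores on both axes and the percentage of variance on each label. Colour marks the group (blue EV, red sgKAT6A) and shape the replicate number (circle 1, triangle 2). The first component, with 61.0% of the variance, runs from EV replicate 1 at -39.6 to sgKAT6A replicate 2 at 54.6, with the EV libraries on either side of sgKAT6A replicate 1.

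KAT6A transcript was lower in both sgKAT6A libraries than in both EV libraries. The gene lies on chromosome 8, positions 41929479 to 42052026, minus strand, in GENCODE 29 on GRCh38. It averaged 11.5 ± 0.979 TPM (SD, n = 2) in sgKAT6A and 16.5 ± 0.387 TPM (SD, n = 2) in EV, a ratio of 0.70. The log2 difference was -0.48 ± 0.13 (SE), with a 95% interval of -0.84 to -0.12, and the adjusted p by limma was 0.784. Within replicate number 1 the KAT6A difference was -0.38, and within number 2 it was -0.58. An edit that disrupts the reading frame need not remove the transcript, so this level does not measure loss of the protein. KAT6B, the closest paralog of KAT6A, was at 5.38 ± 1.35 TPM in sgKAT6A and 4.64 ± 0.774 TPM in EV (SD, n = 2 each, adjusted p = 0.85 by limma). The 8 genes of the MOZ complex had a median log2 difference of -0.01 (camera adjusted p = 0.882).

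No gene passed the threshold between sgKAT6A and EV. With limma, 0 of 12603 genes had an adjusted p under 0.05, the smallest adjusted p was 0.191, and 459 genes had an unadjusted p under 0.05 against 630 expected by chance. Without sgKAT6A replicate 1 that count was 1258, above the expectation, and it was 183 without EV replicate 1, 263 without EV replicate 2 and 299 without sgKAT6A replicate 2. The fit without a block keeps the differences between replicate numbers in its residual variance, which lowers such counts. With the replicate number as a block, 2417 genes had an unadjusted p under 0.05 by limma, although the labels do not pair the libraries. The 459 comprised 210 with higher and 249 with lower values in sgKAT6A. Restricting the table to protein-coding genes and rescaling it gave 259 higher and 106 lower at the same unadjusted level, and leaving out the mean-variance trend gave 265 higher and 197 lower. With 1 library left out, the share with higher values ran from 29.7% without sgKAT6A replicate 1 to 68.8% without EV replicate 2, so the balance of directions depended on scaling, variance model and library. Separation of the groups also depended on the scaling, where chance gives 16.7% in each direction. Of 10807 protein-coding genes, 25.1% had both sgKAT6A libraries below both EV libraries and 13.5% had both above. After the rescaling, which removes the lower protein-coding share of the sgKAT6A libraries, the values were 16.2% below and 19.5% above over 11019 genes. On simulated data with the spread of these libraries and independent noise, the test recovered 33.7% of genes changed 4-fold and 0.6% of those changed 2-fold. Exact permutation of 2 against 2 libraries cannot give a two-sided p below 0.333.

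The genes with the smallest unadjusted p and no overlap of the groups were all microRNAs or small nucleolar RNAs, and none passed. Higher in sgKAT6A were MIR548AI, MIR4738, MIR4740, MIR219A1, SNORD14A, SNORD116-6, MIR185, SNORD59B, MIR616 and SNORD91B. Lower were SNORD116-2, SNORD116-27, MIR8086, SNORD136, SNORA13, SNORD131, MIR4516, MIR3682, MIR4673 and MIR4292. Many were listed at 0 in 1 group and at a few TPM in the other. MIR548AI, for example, was at 0 and 0 TPM in EV and at 7.02 and 6.59 TPM in sgKAT6A. MIR8086 was at 4.54 and 5.06 TPM in EV and at 0 and 0 TPM in sgKAT6A. TPM divides by transcript length, so a few reads of genes this short can give such values, and read depth is unknown. SNORD116-2 had the smallest adjusted p, 0.191 by limma, and was listed at 24.8 and 20.4 TPM in the EV libraries and at 0 in both sgKAT6A libraries. SNORD116-6, a near-identical copy in the same cluster, was listed at 0 in both EV libraries and at 29.1 and 13.3 TPM in sgKAT6A, so the assignment of reads among SNORD116 copies is uncertain. SNORD14A was at 79.9 and 92.7 TPM in sgKAT6A and at 27.4 and 30.5 TPM in EV.

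Among protein-coding genes, the same ordering was applied after the values had been seen, and again none passed (adjusted p = 0.784 by limma for each). UBA7, the activating enzyme for ISG15 conjugation, was at 15.6 ± 0.638 TPM in sgKAT6A against 7.75 ± 0.463 TPM in EV. CST3, which encodes cystatin C and is abundant in monocytes, was at 1472 and 1455 TPM against 958 and 869 TPM. ANXA1, encoding the anti-inflammatory protein annexin A1, was at 83.1 ± 0.581 TPM against 45.8 ± 5.17 TPM. The others with higher values were GPR27, TSPAN32, MS4A4E, LAIR2, AHNAK, HIST1H3B and ADGRE1, with log2 differences from 0.73 for LAIR2 to 1.13 for ADGRE1. On the lower side, BMI1, a Polycomb repressor needed for stem cell self-renewal, was at 56.1 ± 2.01 TPM in sgKAT6A against 79.6 ± 0.799 TPM in EV, a ratio of 0.705. The others with lower values were SHOX2, RAC3, RNF208, RPS29, SLC37A4, DTL, SPATC1L, CDK2AP1 and CDCA7L, with log2 differences from -0.99 for RAC3 to -0.40 for RPS29. BMI1 belongs to the stem and progenitor list, which did not pass (median -0.05, camera adjusted p = 0.882). Of its 14 genes tested, 1 was lower (BMI1) and 3 were higher in sgKAT6A without overlap of the groups (SPINK2, SERPINB1 and ETV6). Values with ± are means and SD with n = 2 per group. Reads of HIST1H3B and RPS29 may be split with near-identical histone genes or pseudogenes.

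**Figure D2:**
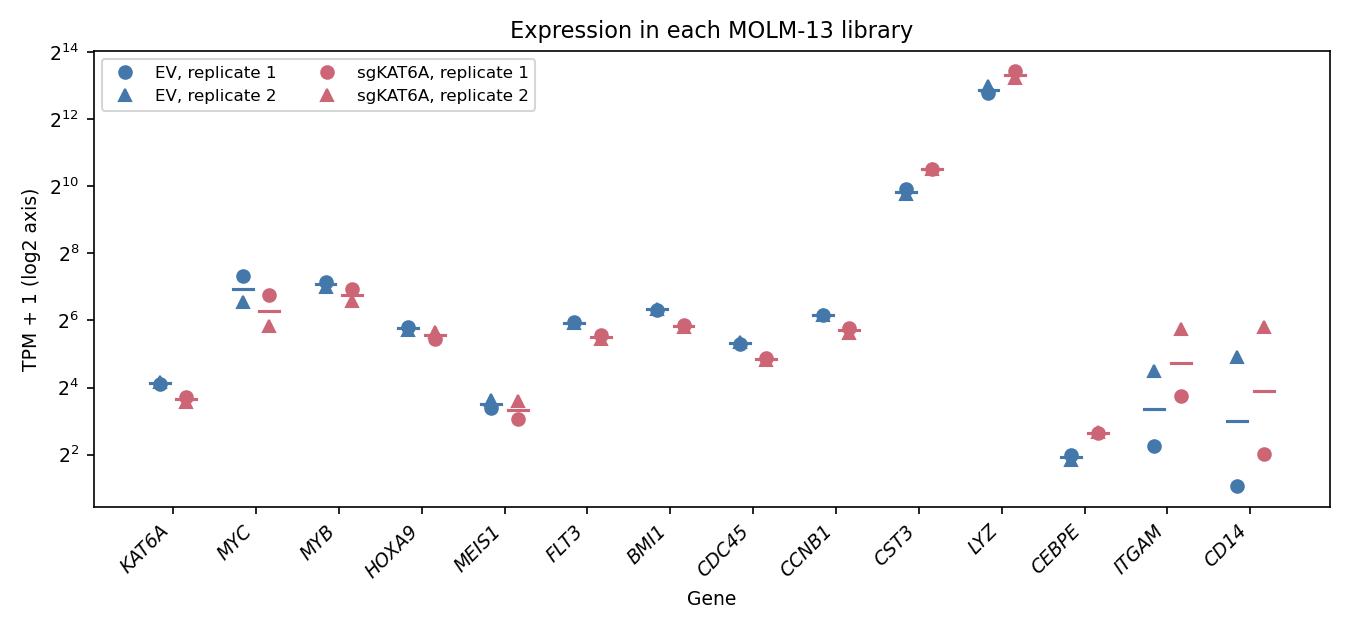
TPM + 1 on a log2 axis for 14 genes in each library, with 1 point per library and a horizontal bar at the mean of the log2 values of each group. Blue is EV and red is sgKAT6A, circles are replicate 1 and triangles replicate 2. KAT6A, MYB, HOXA9, FLT3, BMI1, CDC45 and CCNB1 lie lower and CST3, LYZ and CEBPE lie higher in both sgKAT6A libraries than in both EV libraries. For ITGAM and CD14, both libraries of replicate 2 lie above both libraries of replicate 1.

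MYC targets, cell cycle genes and nuclear genes of the mitochondrial ribosome and of oxidative phosphorylation fell relative to other genes in sgKAT6A. The 56 MYC target genes fell by a median log2 difference of -0.51, and 28 of them had both sgKAT6A libraries below both EV libraries while 0 had both above. The 36 genes of G1/S and DNA replication fell with a median of -0.32, 28 of them without overlap. The 36 genes of G2/M and mitosis fell with a median of -0.21, 19 of them without overlap. The 48 mitochondrial ribosomal protein genes fell with a median of -0.30 (32 without overlap) and the 49 nuclear genes of oxidative phosphorylation with a median of -0.19 (35 without overlap). Camera adjusted p-values with a preset correlation were 6.49e-13, 2.10e-12, 1.71e-06, 7.42e-10 and 3.22e-08 in that order. With an estimated correlation, which leaves 2 residual degrees of freedom, none of these calls held (adjusted p = 0.829 for each). For comparison, 25.1% of all 10807 protein-coding genes were lower and 13.5% higher in sgKAT6A without overlap, in the values as deposited. The oxidative phosphorylation median was -0.16 with median-of-ratios scaling and -0.11 with quantile normalization.

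The examples with the smallest unadjusted p in these lists did not pass as single genes, whether adjusted over all genes or adjusted over the list alone. CDC45, a helicase component of the replication fork, was at 27.8 ± 0.839 TPM in sgKAT6A and 39.0 ± 1.39 TPM in EV (SD, n = 2 each). FEN1, the flap endonuclease, was at 45.1 ± 5.04 against 63.6 ± 1.83 TPM, and MCM2, a subunit of the replicative helicase, at 66.2 ± 8.10 against 91.3 ± 2.83 TPM. CCNB1, the mitotic cyclin B1, was at 51.3 ± 4.06 against 70.6 ± 1.01 TPM, and BUB1, a spindle checkpoint kinase, at 28.9 ± 1.42 against 38.2 ± 0.189 TPM. NPM1, the nucleolar chaperone nucleophosmin, was at 875 ± 111 against 1154 ± 109 TPM. MRPS17 was at 34.5 ± 8.84 against 54.2 ± 4.60 TPM, with a log2 difference of -0.66 that was -0.40 without sgKAT6A replicate 2, and COX6C at 362 ± 23.0 against 458 ± 8.84 TPM. MKI67, the proliferation marker Ki-67, did not follow, at 31.8 ± 5.01 against 30.5 ± 3.18 TPM.

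In size, the medians of these lists exceeded the gap between the EV libraries, but those of MYC targets and mitochondrial ribosomal proteins did not exceed the gap between the sgKAT6A libraries. Between EV replicate 2 and EV replicate 1 the median differences were -0.03 for G1/S, 0.17 for G2/M, -0.36 for MYC targets, -0.16 for mitochondrial ribosomal proteins and -0.08 for oxidative phosphorylation. Between sgKAT6A replicate 2 and sgKAT6A replicate 1 they were -0.23, 0.096, -0.69, -0.33 and -0.15 in the same order. Within replicate numbers 1 and 2, the sgKAT6A differences were -0.25 and -0.41 for G1/S, -0.21 and -0.23 for G2/M, and -0.35 and -0.69 for MYC targets. They were -0.23 and -0.41 for mitochondrial ribosomal proteins and -0.15 and -0.24 for oxidative phosphorylation. Leaving out each library in turn kept all of these calls, with the MYC target median between -0.86 without sgKAT6A replicate 1 and -0.20 without sgKAT6A replicate 2, and the G2/M median between -0.31 without EV replicate 1 and -0.10 without EV replicate 2. The mitochondrial ribosomal protein median was -0.15 without sgKAT6A replicate 2. The G2/M median was -0.12 without sgKAT6A replicate 1. The MYC list contains RRP9 and RRP12, which were at 1.71 and 0.665 TPM in sgKAT6A replicate 2 and above 25 TPM in the other libraries, and its median without ribosomal RNA symbols was -0.50.

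**Figure D3:**
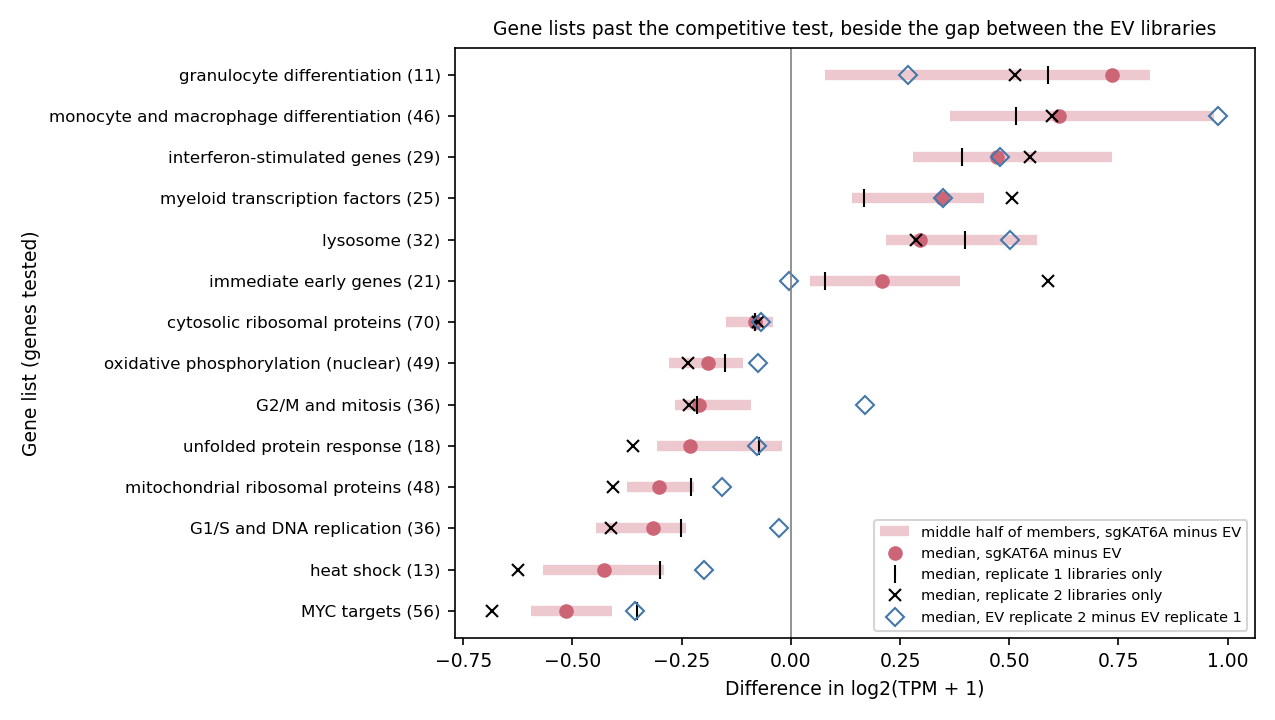
Median difference in log2(TPM + 1) for the 14 gene lists past the competitive test, with the number of genes tested in parentheses. Red points are sgKAT6A minus EV and red bars the interquartile range over members; black marks are the same difference within replicate 1 (bar) or replicate 2 (cross) libraries, and open blue diamonds are EV replicate 2 minus EV replicate 1. MYC targets lie at -0.51 and granulocyte genes at 0.73, and the blue diamond of the monocyte list, at 0.98, lies beyond its red point at 0.61.

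Myeloid differentiation genes rose as lists in sgKAT6A, but for all of them except the granulocyte list the gap between the EV libraries was at least as large as the group difference. The 46 monocyte and macrophage genes rose with a median log2 difference of 0.61, 43 of them higher in sgKAT6A within both replicate numbers and 9 without overlap of the groups. The 11 granulocyte genes rose with a median of 0.73 and a mean of 0.46, with 7 of them higher and 3 lower in sgKAT6A within both replicate numbers. The medians of the other lists that rose were 0.35 for the 25 myeloid transcription factors, 0.30 for the 32 lysosomal genes and 0.47 for the 29 interferon-stimulated genes. Camera adjusted p-values were 1.63e-08, 0.0322, 0.0014, 7.85e-07 and 3.53e-07 in that order, and each was 0.829 as an adjusted p with an estimated correlation. The gap between EV replicate 2 and EV replicate 1 was 0.98 for the monocyte list, 0.27 for granulocyte genes, 0.35 for myeloid transcription factors, 0.50 for lysosomal genes and 0.48 for interferon-stimulated genes. Between the sgKAT6A libraries it was 1.08, 0.28, 0.51, 0.43 and 0.76 in the same order. Within replicate numbers 1 and 2, the sgKAT6A difference was 0.52 and 0.60 for the monocyte list, 0.59 and 0.51 for granulocyte genes, and 0.39 and 0.55 for interferon-stimulated genes. For myeloid transcription factors it was 0.17 and 0.51, and for lysosomal genes 0.40 and 0.29.

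Single myeloid genes varied with replicate number to different degrees, and none passed. LYZ, encoding lysozyme, was at 10238 ± 1043 TPM in sgKAT6A against 7564 ± 713 TPM in EV (SD, n = 2 each). CEBPE, a transcription factor of late granulocyte maturation, was at 5.30 ± 0.0301 against 2.79 ± 0.279 TPM, and CD86, a costimulatory ligand of monocytes and dendritic cells, at 23.5 ± 8.40 against 11.3 ± 4.60 TPM. The CD86 log2 difference of 1.01 was 0.62 without EV replicate 1 and 0.65 without sgKAT6A replicate 2. ITGAM, which encodes CD11b, was at 3.74 and 21.5 TPM in EV replicates 1 and 2 and at 12.3 and 52.1 TPM in sgKAT6A replicates 1 and 2. CD14, the monocyte co-receptor for lipopolysaccharide, was at 1.08 and 29.3 TPM in EV and at 3.04 and 54.3 TPM in sgKAT6A, in the same order. Without EV replicate 1 the log2 difference of CD14 was -1.02 and that of ITGAM 0.24, and without EV replicate 2 they were 2.84 and 2.49. Among interferon-stimulated genes, BST2 was at 284 ± 9.15 against 215 ± 15.6 TPM and IRF1 at 11.9 ± 1.35 against 8.37 ± 0.197 TPM. GFI1, a repressor required for granulocyte development, was on the lower side at 39.0 and 34.5 TPM in sgKAT6A against 46.9 and 45.5 TPM in EV. IRF8, also of the myeloid transcription factor list, was lower too, at 181 and 172 TPM in sgKAT6A against 210 and 214 TPM in EV.

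Of these rises, the interferon-stimulated list alone kept its call when each library was left out in turn, with medians from 0.25 without sgKAT6A replicate 2 to 0.89 without sgKAT6A replicate 1 and 0.80 without EV replicate 2. Without sgKAT6A replicate 2 the monocyte list had a median of 0.13 and an adjusted p of 0.0665 by camera, and the myeloid transcription factor list 0.01 and 0.617. The monocyte median was 0.12 without EV replicate 1, 1.23 without EV replicate 2 and 1.39 without sgKAT6A replicate 1. The myeloid transcription factor median was 0.095 without EV replicate 1 and 0.66 without sgKAT6A replicate 1. The granulocyte call ended without sgKAT6A replicate 1 (median 0.74, camera adjusted p = 0.0912) and without sgKAT6A replicate 2 (0.29, adjusted p = 0.0853), and its median was 0.24 without EV replicate 1. It also ended with no filter on low values (0.24) and with a mean of at least 5 TPM (0.33). The lysosomal call ended without EV replicate 1 (median 0.05, camera adjusted p = 0.0518), and its median was 0.13 without sgKAT6A replicate 2, 0.62 without EV replicate 2 and 0.50 without sgKAT6A replicate 1.

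The HOXA and KMT2A fusion target list did not pass. Its 25 genes had a median log2 difference of -0.16 (camera adjusted p = 0.0596), or -0.15 and -0.062 within replicate numbers 1 and 2, with 11 lower and 2 higher in sgKAT6A without overlap of the groups. The list was called lower with no filter on low values (camera adjusted p = 0.0174), with ribosomal protein genes left out (0.0345), without EV replicate 2 (0.0219) and without sgKAT6A replicate 2 (0.0114), against 0.42 without sgKAT6A replicate 1 and 0.434 without EV replicate 1. FLT3, the receptor tyrosine kinase that is mutated in many myeloid leukaemias, was at 44.6 ± 2.35 TPM in sgKAT6A and 60.2 ± 1.14 TPM in EV (SD, n = 2 each), with a log2 difference of -0.43 ± 0.12 (SE) and an adjusted p of 0.784 by limma. MEF2C was at 22.9 ± 2.47 against 29.3 ± 1.11 TPM. HOXA9, a homeobox gene maintained by KMT2A fusions, was at 46.1 ± 4.75 against 53.2 ± 2.13 TPM, and its cofactor MEIS1 at 9.28 ± 2.64 against 10.4 ± 1.26 TPM. HOXA10 was at 16.8 ± 0.961 against 16.3 ± 1.53 TPM. MYB was at 108 ± 20.2 against 134 ± 10.3 TPM, with a log2 difference of -0.31 that was -0.12 without sgKAT6A replicate 2 and -0.50 without sgKAT6A replicate 1. The HOXA9 difference of -0.21 was -0.10 without sgKAT6A replicate 1 and -0.31 without sgKAT6A replicate 2, and the MEIS1 difference of -0.16 was 0.10 and -0.43. MYC itself was at 107 and 55.7 TPM in sgKAT6A replicates 1 and 2 and at 161 and 93.0 TPM in EV replicates 1 and 2, with a log2 difference of -0.66 ± 0.44 (SE) and an adjusted p of 0.784 by limma. Within replicate numbers 1 and 2 the MYC difference was -0.59 and -0.73. It was -0.19 without sgKAT6A replicate 2, -1.12 without sgKAT6A replicate 1, -0.27 without EV replicate 1 and -1.05 without EV replicate 2.

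Protein folding genes fell as lists. The 13 heat shock genes fell with a median of -0.43 (camera adjusted p = 0.000938; adjusted p = 0.829 with an estimated correlation), 9 of them without overlap, against a gap of -0.20 between the EV libraries and of -0.52 between the sgKAT6A libraries. The heat shock median was -0.30 within replicate number 1 and -0.62 within number 2. HSP90AB1, the constitutive HSP90, was at 833 ± 210 TPM in sgKAT6A against 1139 ± 119 TPM in EV, and its log2 difference of -0.47 was -0.21 without sgKAT6A replicate 2 and -0.73 without sgKAT6A replicate 1. The heat shock median was -0.20 without sgKAT6A replicate 2 and -0.66 without sgKAT6A replicate 1, and the call held in both. The 18 genes of the unfolded protein response fell with a median of -0.23 (adjusted p = 0.0322; adjusted p = 0.829 with an estimated correlation), which was -0.04 without sgKAT6A replicate 2, where the call ended, and -0.38 without sgKAT6A replicate 1. That call also ended without EV replicate 1, with a median of -0.19, and with quantile normalization, with -0.16. The median of this list was -0.072 within replicate number 1 and -0.36 within number 2, and the gap between the sgKAT6A libraries was -0.35. The 70 cytosolic ribosomal protein genes fell with a median of -0.08 (adjusted p = 0.000734; adjusted p = 0.829 with an estimated correlation), about the -0.07 between the EV libraries and the -0.083 and -0.074 within replicate numbers 1 and 2, and the call ended with protein-coding genes only, at -0.02. It also ended without EV replicate 1, at -0.05, and without sgKAT6A replicate 2, at -0.06. The immediate early list was called higher, with a median of 0.21 (camera adjusted p = 0.0437, and 0.829 with an estimated correlation). Of its 21 genes, 9 were higher and 2 lower in sgKAT6A within both replicate numbers, and 3 were higher and 1 lower without overlap. The immediate early median was 0.079 within replicate number 1 and 0.59 within number 2, against a gap of 0.59 between the sgKAT6A libraries. That list was at -0.06 without sgKAT6A replicate 2, 0.54 without sgKAT6A replicate 1 and 0.15 without EV replicate 2, and the first and the last of these ended the call, as did a pseudocount of 0.1, no filter, median-of-ratios scaling and protein-coding genes only.

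The remaining lists did not pass with the planned test. Median log2 differences were 0.86 for MHC class II (camera adjusted p = 0.123), 0.08 for MHC class I (0.123), 0.33 for NF-kB and inflammatory genes (0.151), 0.16 for cell-cycle brakes (0.138) and -0.10 for the integrated stress response (0.0971). MHC class I was called higher with quantile normalization (0.0415) and the integrated stress response lower with no filter (0.017). Within replicate numbers 1 and 2 the medians were 0.33 and 0.31 for NF-kB genes and 0.61 and 0.99 for MHC class II, with 6 of its 7 genes higher in sgKAT6A within both numbers. Leaving out a library, which leaves the numbers unbalanced between the groups, turned the sign of some lists. The NF-kB median was -0.55 without EV replicate 1, -0.64 without sgKAT6A replicate 2, 1.41 without EV replicate 2 (camera adjusted p = 0.000164) and 1.33 without sgKAT6A replicate 1 (0.000986). The MHC class II median was -0.18, -0.42, 1.48 (0.0105) and 1.73 (0.00151) in the same order, and that of cholesterol synthesis 0.17 (0.00957), 0.23 (0.0264), -0.30 (0.00935) and -0.33 (0.0465). The MHC class I median was -0.096, 0.023, 0.32 (0.0106) and 0.22 in that order, and that of cell-cycle brakes 0.096, 0.082, 0.20 and 0.32 (0.0134). The p53 target list was called higher without sgKAT6A replicate 2 (0.0227) and lower without sgKAT6A replicate 1 (0.0203). Medians with all libraries were -0.02 for p53 targets (0.798), 0.03 for the BCL2 family (0.878), -0.05 for stem and progenitor genes (0.882), -0.07 for cholesterol synthesis (0.882) and 0.18 for other lysine acetyltransferases (0.579). The median of other lysine acetyltransferases was 0.080 and 0.0094 within replicate numbers 1 and 2. KMT2A fusion cofactors had a median of 0.01 (0.962) and glycolysis one of -0.0038 (0.878). Among markers of other cell types, the medians were 0.20 for 11 erythroid and megakaryocyte genes (0.672), -0.05 for 5 lymphoid genes (0.878) and 0.18 for 9 dendritic, mast or basophil genes (0.454). With 1 library left out they ran from -0.25 without EV replicate 1 to 0.37 without EV replicate 2 for erythroid and megakaryocyte genes, and from -0.084 without EV replicate 1 to 0.36 without sgKAT6A replicate 1 for lymphoid genes. Dendritic, mast or basophil genes ran from -0.30 without sgKAT6A replicate 2 to 0.87 without sgKAT6A replicate 1, where they were called (camera adjusted p = 0.0326). The test's direction was opposite to the sign of the median for the stem and progenitor, lymphoid, glycolysis and KMT2A cofactor lists. Only 3 epithelial and fibroblast genes reached 1 TPM, too few to test, with a median of 0.15. No mitochondrially encoded gene of that list carried its symbol in the table.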

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

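The fits with protein-coding genes only and without ribosomal RNA symbols were chosen after seeing the data; the others were planned. The number of genes past the threshold was 0 under every alternative but the replicate block, with each replicate left out included (0 to 0). With the replicate block, 15 genes passed, 13 higher and 2 lower in sgKAT6A. All 15 were at least 2-fold apart and were snoRNA, small nuclear RNA or Y RNA genes. SNORD3A had the smallest adjusted p (0.0124 by limma, log2 difference 3.14). Small nuclear RNA genes such as RNU5B-1, RNU5F-1, RNU12 and RNU4-1 were higher too. The 2 lower were SNORD116-2 and SNORD116-27, and SNORD14A was higher (limma adjusted p = 0.0262, 0.0321 and 0.0471, against 0.191, 0.262 and 0.573 without the block). The cause was not tested. The labels do not say that a number marks a shared culture, batch or day, and with 2 pairs the pairing rests on the number alone. Deviations of same-numbered libraries from their group means correlated at r = 0.45 across 12603 genes and at 0.75 across the 10807 protein-coding ones, which are not independent replicates. Under the block 17 lists passed, adding MHC class II, MHC class I and NF-kB. The number of lists past the threshold, 14, was 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.746, and 0.529 for change in either direction). It was 12 to 19 with 1 library left out and 12 to 14 under the other scalings, filters, pseudocounts and variance models. Leaving aside the estimated correlation and fry, the 14 lists lost a call 18 times with the same direction and 1 time with a reversed one; the cause was not tested. Those called throughout, apart from the estimated correlation and fry, were MYC targets, G1/S, G2/M, mitochondrial ribosomal proteins, oxidative phosphorylation, heat shock and interferon-stimulated genes. Some lists share members, so their calls are not independent. The MYC target list holds MCM4, MCM5 and UNG of G1/S, PLK1 of G2/M, and HSPD1 and HSPE1 of heat shock. The myeloid transcription factor and immediate early lists share EGR1, EGR2, FOS, JUN, JUNB, ATF3, KLF6 and NR4A1. Calls gained with a filter, scaling or composition changed were the HOXA and KMT2A fusion targets, the integrated stress response and MHC class I. With 1 library left out, NF-kB, MHC class II, MHC class I, cholesterol synthesis, p53 targets, cell-cycle brakes, the integrated stress response, dendritic and mast or basophil markers and the HOXA and KMT2A fusion targets were each called at least 1 time, and cholesterol synthesis and p53 targets in both directions. KAT6A stayed lower throughout (log2 difference -0.56 to -0.40 with a library left out, -0.38 with a pseudocount of 5). With a library left out, which leaves a lone sample assumed to vary like the other group, signs turned for CD14 (-1.02 to 2.84), HOXA10 (-0.046 to 0.14), KAT6B (-0.051 to 0.38), MEIS1 (-0.43 to 0.10), MKI67 (-0.10 to 0.21) and the immediate early list (-0.057 to 0.54), and among lists not called for NF-kB (-0.64 to 1.41), MHC class II (-0.42 to 1.73), MHC class I (-0.096 to 0.32), cholesterol synthesis (-0.33 to 0.23), p53 targets (-0.22 to 0.10), dendritic and mast or basophil (-0.30 to 0.87), erythroid and megakaryocyte (-0.25 to 0.37) and lymphoid markers (-0.084 to 0.36), stem and progenitor genes (-0.14 to 0.11), the MOZ complex (-0.092 to 0.052), the BCL2 family (-0.068 to 0.072), glycolysis (-0.039 to 0.039) and KMT2A fusion cofactors (-0.016 to 0.045). The share of higher values among genes with an unadjusted p under 0.05 was 45.8% as reported, 60.4% with median-of-ratios scaling, 55.9% with quantile normalization, 57.4% with no mean-variance trend, 71.0% with protein-coding genes only, 37.0% with a mean of at least 5 TPM, 37.1% with ribosomal protein genes left out, and 29.7% to 68.8% with a library left out. Those genes numbered 183 to 1258 with a library left out and 2417 with the block. Read depth is unknown, so its limit on low genes could not be computed.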

Other observations

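All tests in this part were chosen after the results had been seen. NF-kB, MHC class II and monocyte genes were higher in the libraries numbered 2. With the group as a term in limma, 540 of 12603 genes differed between replicate numbers 2 and 1 at an adjusted p under 0.05, 483 higher and 57 lower in number 2. In the limma fit without that term, 0 genes passed by replicate number, as by group. Those with an unadjusted p under 0.05 then numbered 1411 by replicate number and 459 by group. The 540 therefore compare with the group calls under the replicate block, not with the 0 of the fit without it. The genes named here were picked by size after their values were seen. MMP9, a secreted gelatinase, was at 1.02 and 2.40 TPM in the number 1 libraries (EV, sgKAT6A) and at 85.1 and 212 TPM in number 2. C3, the central complement component, was at 3.49 and 19.5 TPM against 191 and 266 TPM. CTSG, a primary granule protease of early myeloid cells, was at 653 and 408 TPM in number 1 and 157 and 78.6 TPM in number 2, and ELANE, neutrophil elastase, at 1494 and 1162 TPM against 607 and 564 TPM. As lists, without the group term, NF-kB genes differed by a median of 1.95 (camera adjusted p = 7.79e-18), monocyte genes by 1.18 (5.91e-15), MHC class II by 1.83 (5.38e-07), cholesterol synthesis by -0.51 (4.81e-11) and MYC targets by -0.54 (1.68e-11).

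A hypothesis is that the libraries of number 2 were further along a monocyte-like course and that the sgKAT6A libraries lay further along the same course. The monocyte list's median number contrast of 1.18 prompted it and so does not bear on it. Of the 14 lists called by group, 12 had a number median of the same sign (not G2/M and not the granulocyte list, at -0.07). The contrasts correlated at r = 0.65 across protein-coding genes. A deviation of sgKAT6A replicate 2 or of EV replicate 1 alone moves both contrasts the same way, so neither value decides it. G2/M genes did not follow the hypothesis. Their medians were lower in sgKAT6A within both replicate numbers (-0.21 and -0.23) and higher in number 2 within both groups (0.17 in EV, 0.096 in sgKAT6A). Their median number contrast was 0.13, with 27 of 36 members higher in number 2. This list was weighed after its opposite sign had been seen, so its values describe G2/M genes only and do not decide the hypothesis. The granulocyte list was not called by replicate number (camera adjusted p = 0.585), so its opposite sign does not decide it. A different share of non-coding RNA in the TPM total is argued against for the NF-kB median of 1.95, because the protein-coding share differed between numbers by 0.0066 on the log2 scale. A difference of batch, harvest or culture between the numbers stays open, since the labels name none and the 540 genes cannot be told apart by their cause.

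The 4 libraries can be split into groups of 2 in 3 ways, too few for a share under 0.05. The real split called 14 lists, the split by replicate number 21 (the highest of the others) and the crossed split 7. The lists of the crossed split included immediate early genes (camera adjusted p = 8.50e-07, against 0.0437 by group), myeloid transcription factors (0.000654), interferon-stimulated genes (0.00798) and cytosolic ribosomal proteins (0.0161), all called by group as well. In the crossed split G1/S was not called (camera adjusted p = 0.369), nor were MYC targets (0.24), G2/M (0.962) or oxidative phosphorylation (0.962). Of the lists called by group, all but the granulocyte list (0.585) were also called by replicate number. G1/S was among them (0.034, median -0.12), and G2/M was called in the opposite direction (0.0256, median 0.13).

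Transcripts of several genes were nearly missing from sgKAT6A replicate 2 alone. In that library 59 genes lay under 0.25 of the lowest other library (others at least 3 TPM), against 34, 8 and 10 in EV replicate 1, EV replicate 2 and sgKAT6A replicate 1. The 12 protein-coding ones were EMG1, FTSJ1, MRM2, RRP1, RRP12, RRP1B, RRP36, RRP7A, RRP8, RRP9, SMIM11B and SMN2, and RRP1B, for example, was at 29.1, 24.5 and 22.0 TPM in the others and 0.289 TPM there. The last pair have near-identical copies, and RRP stands for ribosomal RNA processing. Removal of all ribosomal RNA reads from that library is argued against, since 30.8% of 13 ribosomal RNA genes lay under 0.25 of EV replicate 2, while RNA5S1 was at 14569 against 3924 TPM and RNA28SN1 at 3098 against 4568 TPM. The 4 under that bound were RNA18SN5 (340 against 13751 TPM), RNR1 (187 against 3641), RNR2 (364 against 6881) and RNA28SN2 (0 against 158). Removal under part of the ribosomal RNA names stays open and was not decided: the 8 RRP genes lay 3.36 below 10 UTP genes in median log2 difference from EV replicate 2, but 7 of the 8 are among the genes picked above as nearly missing, so the gap restates the pattern. The fall was not shared to a like degree by sgKAT6A replicate 1. The 16 protein-coding genes at under 0.25 of EV replicate 2 in sgKAT6A replicate 2 had a median log2 difference of -3.66 there. Between the number 1 libraries their median was -0.27, or 7.25% of that fall. They include the 12 already picked as low in sgKAT6A replicate 2 alone, so this gap largely restates the pattern. It does not decide whether a response to KAT6A targeting contributed.

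SNORD3A, the U3 snoRNA, was at 186 and 1583 TPM in EV and sgKAT6A replicate 1 and at 2273 and 20702 TPM in replicate 2. The signal recognition particle RNA RN7SL1 was at 7195, 4608, 4673 and 17557 TPM in EV replicate 1, sgKAT6A replicate 1, EV replicate 2 and sgKAT6A replicate 2.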
